A study of Drosophila melanogaster with 2 samples.

How the data were processed

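ChIP-seq was done on chromatin of whole embryos of 0 to 24 h, fragmented by sonication to 200 to 800 bp, per the labels. The 2 samples are biological replicates 1 and 2 of the same group, per the labels. Per the deposited inventory files, peaks were called on the alignments of each replicate and on their pool against 1 control, and the IDR-thresholded set was made from these lists. The aligner, the peak caller and their versions are not given in the sources used here. The control was not analysed here. Lists were given on builds dm6 and dm3.

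Each deposited list gives a peak's start and end, the summit, a signal value and the −log10 of its q-value. The signal is the deposited value of the peak caller, is not stated to be normalized to depth, and was used to rank peaks within a list. Between the replicate lists it was correlated, and levels were not compared. The deposited −log10 q saturated at 3.89 in 3851 of the 30000 pooled dm6 peaks, so peaks were ranked by signal. The dm6 thresholded set was found to be the 4537 peaks of highest signal in the pooled list, unchanged. An alternative that takes the strongest pooled peaks therefore uses the same peaks. The lists hold no read counts, so the depth of the samples is unknown, and intervals given for shares and odds ratios cover counting error over peaks only. A weak site missing from a list cannot be told from an unbound one.

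Positions are on dm6 and were annotated with the Release 6 genome and Ensembl release 115 (BDGP6.54). Chromosome lengths were checked against the largest peak ends. The dm3 lists were used for counts and for agreement between replicates, and no position was converted. In the 2 builds, 4537 and 4430 summits passed the threshold. Each summit was put in the first class that applied: promoter (within 500 bp of a TSS of a protein-coding gene), 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic. The background was the 24584 relaxed pooled peaks that overlap no thresholded peak.

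Replicate overlap counted summits within 100 bp and was tested with 9999 circular shifts. Location classes, the X share, 7-mers and motifs were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family, and 0.5 was added to each cell for odds ratios. Windows of 201 bp were matched to relaxed windows in GC bins of 2%. Windows 400 bp to the side of the same summits, used as an alternative, were neither matched on GC nor paired in the test. A 7-mer was called at an adjusted p under 0.05 and an odds ratio of at least 1.5 or, for depletion, the inverse. A gene was bound if a thresholded summit lay within 1000 bp of a TSS, and list counts were tested with 100000 draws of genes matched on span (3 groups) and number of TSSs among genes with a relaxed summit. The 15 lists written by hand hold 219 entries, in which a gene on more than 1 list counts each time, and 4 entries had another symbol in the annotation. The ribosomal protein genes were taken by symbol. Signal of promoter and distal peaks was compared with 100000 permutations.

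Named genes followed a rule fixed before the data were examined: chn, ac, sc, l(1)sc, Dl and N, the 12 genes with the strongest promoter peak, the 5 strongest peaks farther than 1000 bp from a TSS, the 3 members of each list with the strongest promoter peak, and the 10 7-mers of smallest p. Alternatives covered a stricter set of 1000 peaks, each replicate alone, other distances, other backgrounds and other window sizes. Peaks on heterochromatic and unplaced scaffolds of dm3 entered no comparison.

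The tests were tested on simulated data. A 7-mer planted in 2% of random windows was found among 8192 with no other call, and with none planted no call was made. Planted in 5%, it was found with 4 other calls. Both sets in these runs were random bases drawn from the same GC contents. Differences in genomic sequence or location class between sets were therefore not simulated. A raised promoter share was called. A separate comparison of random positions with no share raised gave no call. Of 10 raised gene lists among 40, all 10 were called, with 1 list that was not raised. An overlap planted at 50.3% of 1500 summits gave 756 shared summits. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.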

Results

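The data are peak lists of chromatin immunoprecipitation with sequencing (ChIP-seq) on whole Drosophila melanogaster embryos of mixed sex, collected 0 to 24 h after egg laying. The embryos came from a transgenic line that makes charlatan, the zinc finger transcription factor encoded by chn, with GFP fused to its C-terminal end. An antibody against GFP was used for the precipitation. There was 1 group of 2 biological replicates, so no condition was contrasted with another. The comparisons were between the replicates, and between the peaks that passed the irreproducible discovery rate (IDR) threshold and the weaker peaks of the relaxed list. On build dm6 the thresholded set held 4537 summits in 4532 intervals, and each relaxed list held 30000 summits. The lists give no read totals, so the depth is unknown. Signal values are the authors' own and were used to rank and describe peaks within a list. Between the replicate lists they were correlated, and differences in level between lists were not interpreted. Tests over peaks or genes treat these as units and do not measure the spread between embryos.

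The replicates shared most of their strong binding sites. Of the 4537 strongest summits of replicate 1, 3269 (72.1%) lay within 100 bp of a summit among the 4537 strongest of replicate 2. Circular shifts of the replicate 2 summits along each arm gave 0.688% on average (one-sided permutation test, p = 0.0001, the smallest that the shifts can give). Random peaks of the replicate 2 relaxed list, a comparison added after the data were seen, gave 13.8%. Among the 1000 strongest summits of each replicate, 79.0% were shared. The strongest peak of all, at the promoter of CG14100, ranked 2 in replicate 1 and 1 in replicate 2. The strongest peak farther than 1000 bp from a TSS, nearest to cbt, ranked 1 and 2.

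Across the 4534 thresholded peaks matched in both replicate lists, the signal values had a Spearman rho of 0.763 (bootstrap interval 0.748 to 0.778) and a Pearson r of log2 signal of 0.840. These correlations are across peaks, which are not independent replicates, and no p-value was computed. The thresholded set was also built from these same replicates. Both replicates placed 3285 of the 4537 thresholded summits (72.4%) among their own strongest 4537, and 77 were in neither.

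**Figure D1:**
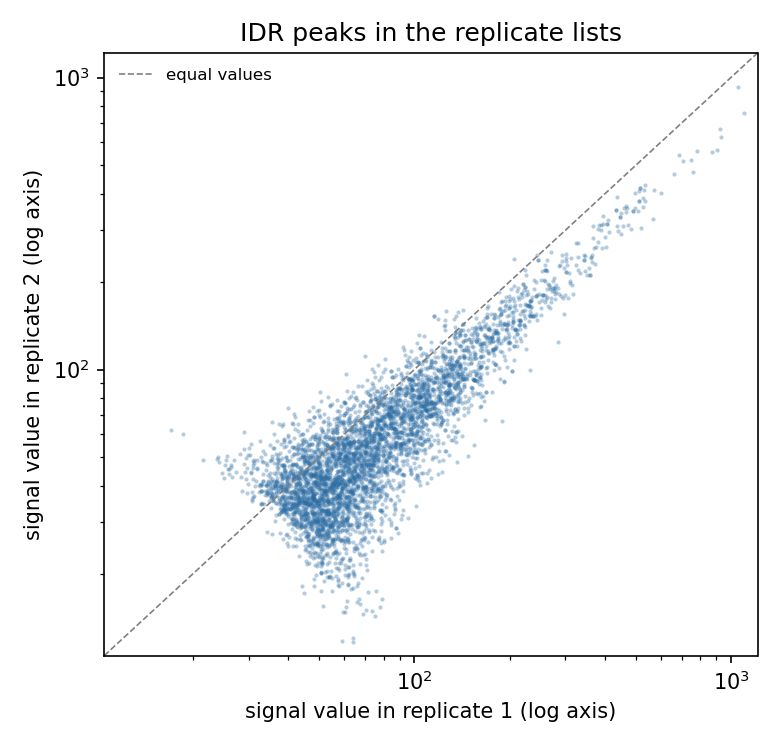
Signal value of each thresholded peak in the replicate 1 list (x axis) and in the replicate 2 list (y axis), both on log axes, with 1 point per peak and a dashed line at equal values. The points rise together, with a Spearman rho of 0.763, and spread more at low signal.

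Binding was concentrated at promoters and nearly absent from coding exons. Of the 4537 thresholded summits, 2345 (51.7%) lay within 500 bp of a transcription start site (TSS) of a protein-coding gene, against 21.7% of the 24584 relaxed summits outside thresholded peaks. The odds ratio was 3.85 (95% interval 3.61 to 4.11, counting error only), and Fisher's exact test gave an adjusted p too small for double precision to hold. Only 15 summits (0.331%) lay in coding exons outside promoters, against 15.9% of the relaxed summits (odds ratio 0.0181, 95% interval 0.0110 to 0.0298, Fisher's exact test, adjusted p = 1.17e-280). Random positions on the major arms fell in promoters in 11.6% of cases and in coding exons in 13.8%.

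Introns held 1405 of the thresholded summits and 37.1% of the relaxed ones (odds ratio 0.760, Fisher's exact test, adjusted p = 2.61e-15). Intergenic sequence held 13.8% and 20.1% (odds ratio 0.636, exact test, adjusted p = 2.89e-24). The 3' UTR share was 0.727% against 1.79% (exact test, adjusted p = 2.71e-08), and the 5' UTR outside promoters held 30 thresholded summits, an odds ratio of 0.556 (adjusted p = 0.00107). Other exons, at 1.87% and 2.19%, did not pass the exact test (adjusted p = 0.199). Windows around thresholded summits had a mean GC content of 38.8%, against 45.7% around relaxed summits. With relaxed peaks matched on GC, an alternative added after the data were seen, coding exons held 5.16% of the background and their odds ratio was 0.0629.

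**Figure D2:**
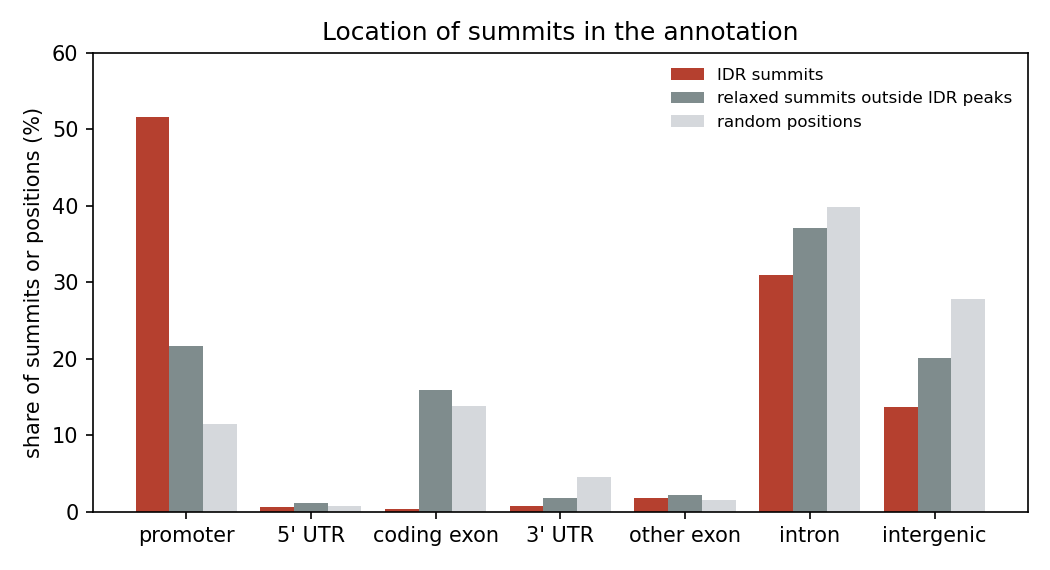
Share of summits or positions (y axis, percent) in each annotation class (x axis) for thresholded summits, relaxed summits outside thresholded peaks and random positions. Promoters hold 51.7% of thresholded summits and 21.7% of relaxed ones, and coding exons hold 0.331% and 15.9%.

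Promoter peaks had slightly higher signal than the others. The median signal value was 117 for the 2345 promoter peaks and 108 for the 2192 other peaks, a ratio of 1.08 (two-sided permutation test with 100000 resamples, p = 2.0e-05). Among the 1000 strongest peaks the ratio was 1.04 and did not pass the permutation test (p = 0.185).

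The strongest promoter peaks lay at genes with a range of cellular roles. The rule for named genes took 12, whose signal values ran from 968 to 1972 and which ranked 17 or better in replicate 1 and 15 or better in replicate 2. The highest was at CG14100 (FBgn0036889, 3L, 19590427 to 19590817, signal 1972, summit 96 bp from a TSS). It was followed by px, a regulator of wing vein pattern (2R, 22514109 to 22514511, signal 1586), and by Chro, which encodes the chromatin and spindle protein Chromator (3L, 22878694 to 22879101, signal 1551). The peak at Ugalt, a UDP-galactose transporter (X, 2703711 to 2704075), had a signal of 1462. The peak at CHMP2B, an ESCRT-III component (3L, 5139321 to 5139689), had a signal of 1343. Peaks at PNPase, a mitochondrial polynucleotide phosphorylase (3R, 31404476 to 31404835), and Lk6, a kinase of the translation factor eIF4E (3R, 11760866 to 11761226), had signals of 1265 and 1227. The remaining genes were CG1888, the Polycomb group gene ph-p, CenG1A, CG8320 and the arginine methyltransferase gene Art3. Of the 12 summits, 11 were within 500 bp of a TSS. The Lk6 summit was intronic, 963 bp from a TSS. At 7 of the 12 a TSS of another gene lay within 1000 bp, for example Ssl1 beside Chro and mRpS10 beside Art3, so the peak cannot be assigned to 1 gene.

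The 5 strongest peaks farther than 1000 bp from a TSS included 3 in introns. The strongest, in an intron and with its nearest TSS that of cbt, which encodes the zinc finger factor cabut, had a signal of 1865 (2L, 480850 to 481328, summit 1408 bp from the TSS). Peaks nearest to CG11050 (2L, 6612498 to 6612918, intron) and CG32772 (X, 4910205 to 4910571, intron) had signals of 1417 and 1006. Intergenic peaks lay 11912 bp from CG13323 (2R, 13035166 to 13035515, signal 924) and 3161 bp from tara (3R, 16222347 to 16222653, signal 900).

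The locus of the tagged gene itself held many peaks. The gene chn (FBgn0015371) spans 2R from 15115236 to 15144783 on the plus strand and held 13 thresholded summits, 12 in introns and 1 in a promoter. The strongest had a signal of 782 and ranked 38 of all 4537. It lay at 15128692, 134 bp from an internal TSS of chn, in an interval from 15127949 to 15128898 that held a second summit with a signal of 396. Neighbouring intervals also overlapped from 15129596 to 15130175 and from 15132310 to 15133233. The 13 summits therefore stand for a smaller number of separate sites. Upstream of the gene, 2 further summits lay at 15114565 and 15100745, the latter 14491 bp from the TSS. Windows as long as the gene (29548 bp) had a median of 0 thresholded summits over 13241 positions, and 1 window elsewhere held as many as chn.

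**Figure D3:**
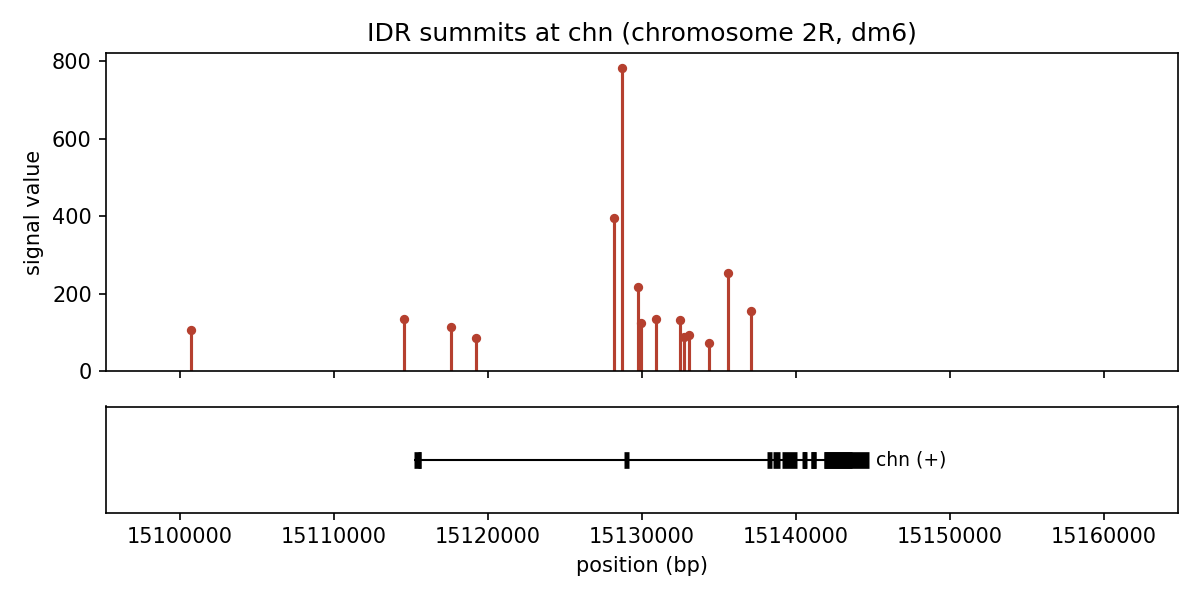
Thresholded summits within 20 kb of chn on chromosome 2R (x axis, dm6 position in bp) with their signal values (y axis), above the gene's annotated exons, drawn as boxes. The highest summit, with a signal of 782, lies beside an internal exon, and 13 of the 15 summits lie inside the gene.

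The proneural genes of the achaete-scute complex had no thresholded peak nearby. These genes, ac, sc and l(1)sc, encode helix-loop-helix factors that start neural precursor formation, and they form a multigene cluster on X. The nearest thresholded summit lay 123056 bp from ac, 96506 bp from sc and 83186 bp from l(1)sc. Within 2000 bp each had 1 relaxed summit, and the strongest of these, at l(1)sc, ranked 13751 of the 30000 pooled peaks. The Notch ligand gene Dl (Delta, FBgn0000463, in the annotation used) had 9 relaxed summits and no thresholded one within 2000 bp, and its nearest thresholded summit was 76993 bp away. The receptor gene N (FBgn0004647) held 1 thresholded summit, with a signal of 309 and a rank of 305, which was not within 1000 bp of a TSS of N. The lists cannot show whether weaker binding at these genes was below detection.

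A thresholded summit lay within 1000 bp of a TSS of 3370 protein-coding genes, 40.0% of the 8422 with a relaxed summit there. Of 16 gene lists fixed before the data were examined, the cytoplasmic ribosomal proteins passed the test. They had 62 of 83 members bound, against 33.8 among genes matched on span and number of TSSs (ratio 1.84, two-sided permutation test with 100000 resamples, adjusted p = 0.00032, where the raw p of 2.0e-05 is the smallest that the resamples can give). The ratio was above expectation in both replicates taken alone, at 1.80 and 1.87. The members with the strongest peaks were RpS27 (3R, 25247386 to 25247665, signal 482), RpL7 (2L, 10200902 to 10201152, signal 453) and RpL34b (3R, 9401181 to 9401419, signal 408), each with another gene's TSS within 1000 bp. Genes that share a promoter count separately in the test, and matched genes were not chosen by shared promoters. With the 1000 strongest peaks the list no longer passed (ratio 1.85, permutation test, adjusted p = 0.0829), and over all alternatives the ratio ran from 1.69 to 2.84.

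The other 15 lists, each with fewer members than the ribosomal one, did not pass. EGFR and FGFR signalling had 11 of 13 members bound against 5.89 expected (permutation test, adjusted p = 0.0611). Its members included the ligand gene spi (signal 514), Ras85D (signal 176, with a TSS of Rlb1 within 1000 bp) and the repressor gene aop (signal 166). It passed with all protein-coding genes as background (permutation test, adjusted p = 0.0121), without strata (adjusted p = 0.0211) and with gene spans in place of promoters (adjusted p = 0.0499). Over its alternatives the ratio ran from 0.578, with the 1000 strongest peaks, to 2.22, with adjusted p-values up to 0.994 by the permutation test. Corepressors had 8 of 9 bound against 4.37 expected (permutation test, adjusted p = 0.112), with gro (signal 486), ebi (signal 333, with a TSS of AP-2alpha within 1000 bp) and Sin3A (signal 259) highest, and passed without strata (adjusted p = 0.0433, the lowest of alternatives that reached 0.994). The Notch pathway, which shares gro with that list, had 9 of 19 bound against 7.08 expected (permutation test, adjusted p = 0.555). Its next strongest members were mam (signal 342) and E(spl)m7-HLH (signal 182), the latter in the E(spl) multigene cluster. Its member dx was bound through a peak 777 bp from its TSS and 34 bp from a TSS of RpL7A, which also counts as bound among the ribosomal genes.

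Of the 16 lists, 11 had fewer bound members than expected and 5 had more, and the lists of neural genes were among the 11 without passing the test. Neuroblast transcription factors had 2 of 15 bound, SoxN (signal 125) and zfh1 (signal 124), against 6.66 expected (ratio 0.300, permutation test, adjusted p = 0.112). Without replicate 2, 5 of 15 were bound and the ratio was 0.752. Neuronal function had 3 of 14 bound, elav (signal 466), Nrx-1 (signal 147) and Syx1A (signal 101.9, with a TSS of CG10694 within 1000 bp), against 6.61 expected (permutation test, adjusted p = 0.268), and passed as lower with all protein-coding genes as background (ratio 0.283, adjusted p = 0.0121, the lowest of alternatives that reached 0.994). The proneural and sensory organ precursor list had 3 of 14 bound against 5.58 expected (permutation test, adjusted p = 0.489). These were neur (signal 156, nearer to a TSS of hyx), numb (signal 143) and da (signal 108). Glia had 4 of 11 bound against 4.88 expected (ratio 0.820), with moody (signal 439), Gs2 (signal 222) and Gli (signal 87.0) strongest. Its ratio was above 1 in 4 of 9 alternatives, at 1.40 with the 1000 strongest peaks, 1.099 without replicate 1, 1.03 with gene spans and 1.01 with all protein-coding genes as background.

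Lists of other tissues did not pass the test either. Muscle had 5 of 16 bound against 7.90 expected, with sls (signal 302), tin (signal 172) and Tm1 (signal 126) highest. Segmentation had 5 of 19 against 7.55, with ptc (signal 146), gsb (signal 126) and opa (signal 119). Gut and endoderm had 2 of 8 against 3.63, bowl (signal 333) and fkh (signal 166). Epidermis and cuticle had 3 of 10 against 4.76, sn (signal 108), Ddc (signal 100.8) and tyn (signal 72.8). Trachea had 2 of 8 against 3.31, bnl (signal 96.1) and rib (signal 93.7). Hemocyte had 1 of 6 against 2.80, ush (signal 177), a ratio of 0.357 that was 0.640 without replicate 1. Hox had 1 of 7 against 3.18, Dfd (signal 84.7), a ratio of 0.314 that was 0 without replicate 2 (0 of 8, permutation test, p = 0.00932, adjusted p = 0.0746). Germline had 4 of 7 against 2.64, with gcl (signal 101.7), nanos (signal 95.7) and piwi (signal 85.5) strongest, and its ratio of 1.52 was 0.832 without replicate 1. The gcl and nanos peaks were nearer to TSSs of CG14767 and CG11779, and a TSS of CG12253 lay within 1000 bp of the piwi peak. Adjusted p-values of these lists and of glia ran from 0.489 to 0.824 (permutation test).

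**Figure D4:**
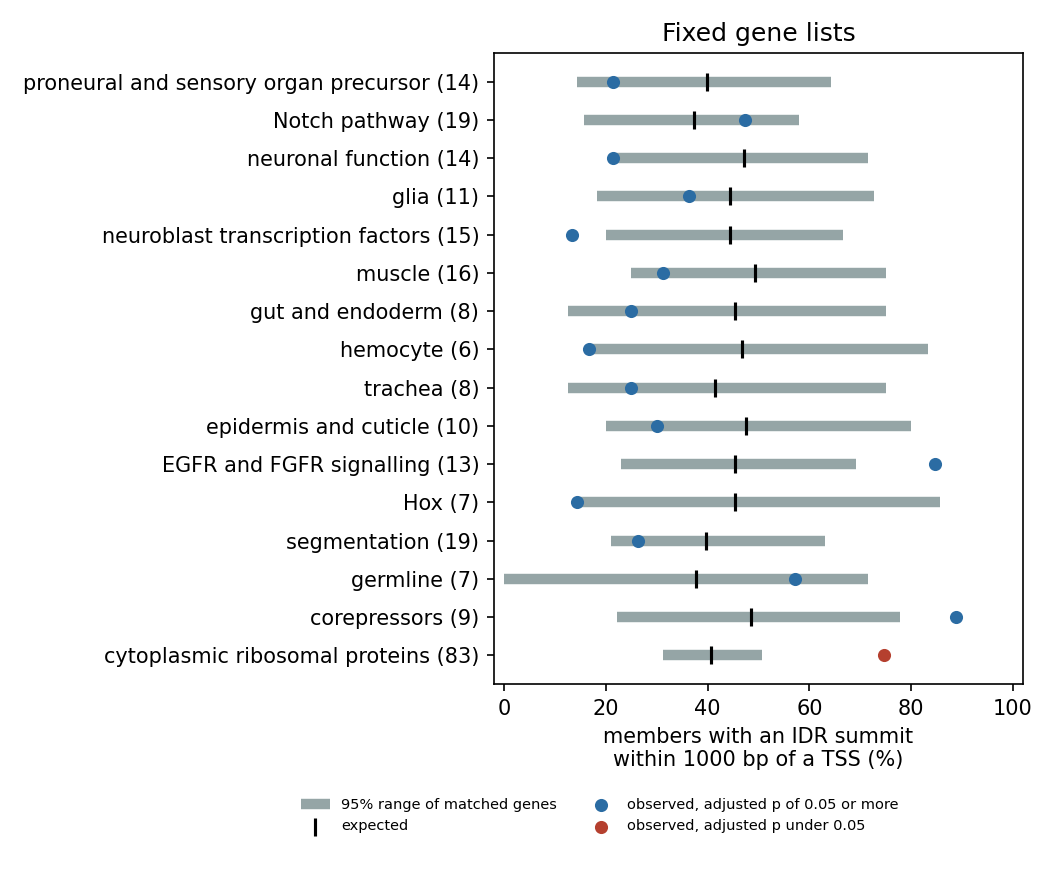
Share of each list's members with a relaxed summit (number in parentheses, y axis) that had a thresholded summit within 1000 bp of a TSS (x axis, percent). Dots are observed shares, ticks the expected share and bars the 95% range of matched genes. Cytoplasmic ribosomal proteins, at 74.7% against 40.7% expected, passed the test.

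The X chromosome held 813 thresholded summits (17.9%), against 16.1% of the relaxed ones (odds ratio 1.14, 95% interval 1.05 to 1.24, Fisher's exact test, p = 0.00279). Against random positions the odds ratio was 1.02 (exact test, p = 0.563), and among the 1000 strongest peaks it was 1.04 (p = 0.693). Density was 34.5 summits per Mb on X and lay between 32.5 and 37.0 on 2L, 2R, 3L and 3R. Chromosome 4 had 12 summits, or 8.90 per Mb.

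Short sequences set the thresholded summits apart from relaxed ones of the same GC content. Of 8192 distinct 7-mers, 154 were enriched within 100 bp of summits and 165 were depleted. The windows were matched on GC content alone. Other differences in sequence composition and in location between the sets were not removed and may contribute to both counts. In a GC-matched background 22.3% of summits were at promoters, against 51.7% of thresholded ones. Comparisons with relaxed peaks of the same location, added after the data were seen, held fewer peaks. They gave 31 enriched 7-mers at promoters, 26 of them among the 154, and 35 farther than 1000 bp from a TSS, 22 of them among the 154. With this draw of the background the smallest p belonged to ACAGTGG, found in 422 of 4537 windows (9.30%) against 205 background windows (4.52%), an odds ratio of 2.16 (95% interval 1.82 to 2.57, Fisher's exact test, adjusted p = 1.46e-15). The next were ATCGATA (odds ratio 2.02), AGTGTTG (2.16), ACAGCTG (2.16), ACTATCG (2.41), CTCGCTC (2.49), CACAGTG (2.01), CTATCGA (2.13), CGCTCTC (2.22) and CGATAGC (2.501). These 10 were enriched in all of 20 other random draws of the background, over which the number of enriched 7-mers ran from 133 to 177. The draws were matched on GC alone as well, so they do not test the difference in location. The number of depleted ones ran from 98 to 144 and was below that of enriched ones in each of the 20. The order of the 7-mers depended on the draw: CTCTCTC, named here after its values were seen, had the smallest p with the same peaks and another draw, and also without replicate 2. Within 50 bp of the summit 73 were enriched.

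Of 17 motifs fixed before the data were examined, 6 passed the test. The DNA replication-related element (DRE) had an odds ratio of 2.56 (Fisher's exact test, adjusted p = 3.67e-13), the GAGA repeat 1.91 (adjusted p = 4.42e-10), core promoter motif 1 1.56 (adjusted p = 0.00431), the E-box CAGCTG 1.40 (adjusted p = 1.07e-05) and the N-box 1.18 (adjusted p = 0.00449). Over 20 other draws of the background the odds ratio of GAGA was higher, from 1.956 to 2.61, and the N-box passed in 18. The N-box did not pass within 50 bp of the summit (1.15) or among the 1000 strongest peaks (1.26). Windows 400 bp to the side of the same summits were not matched on GC, and the N-box was at 0.986 against them. The TTK site was common in both sets and less frequent at thresholded summits, in 22.5% against 28.8% of windows. Its odds ratio was 0.717 (exact test, adjusted p = 5.08e-11), and it passed in all 20 other draws, from 0.684 to 0.756. The matching was on GC content alone, so a remaining difference in sequence composition between the sets may contribute to this deficit. That was not tested. In comparisons added after the data were seen, DRE did not pass among promoter peaks against promoter relaxed peaks (1.18) or among the 1765 peaks farther than 1000 bp from a TSS (0.522), and core promoter motif 1 was at 0.977 and 0.866. Of the 217 thresholded windows with DRE, 209 were at promoter peaks, as were 132 of the 139 with core promoter motif 1. The excess of these 2 motifs in the full set thus went with the larger promoter share of the thresholded peaks. GAGA passed among promoter peaks and among the peaks farther away, at 1.64 and 2.26. The E-box CAGCTG passed among promoter peaks (1.40) and not among the peaks farther away (0.974), and the N-box passed among the latter (1.31) and not among promoter peaks (1.12). Among the 1000 strongest peaks DRE did not pass, with an odds ratio of 1.21 (exact test, adjusted p = 0.687). The left and right arms of the RE1 element, bound by the vertebrate repressor REST, were each as rare in both sets, in 5 against 6 and 11 against 12 windows. The class C site, E-box CAGGTG, Zelda, Su(H), twist, core promoter motif 6, CTCF, ETS and GATA sites did not pass in this comparison. The class C site passed as enriched without replicate 2 (1.33) and as depleted against the side windows (0.790), where CAGGTG also passed as depleted (0.744). CTCF passed without replicate 1 (1.89) and in 5 of the 20 other draws, and core promoter motif 6 in 2.

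**Figure D5:**
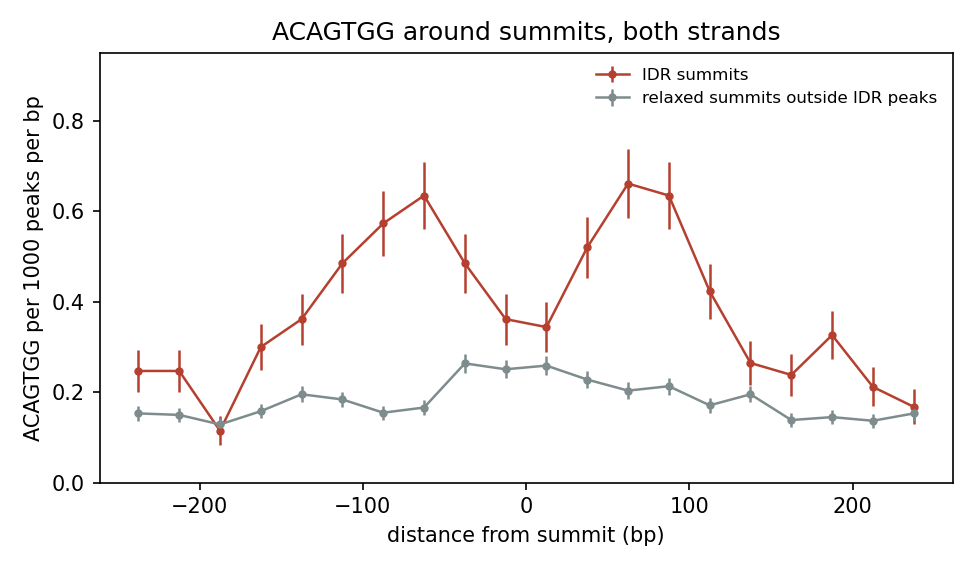
Copies of ACAGTGG on either strand per 1000 peaks and bp (y axis) by distance from the summit (x axis, bp, in bins of 25 bp) for thresholded and relaxed summits, with bars of the square root of each count. Thresholded summits have maxima on both sides, at 0.635 and 0.661, and 0.361 and 0.344 in the bins beside the summit.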

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

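In the dm3 lists, 35 relaxed pooled peaks lay on heterochromatic or unplaced scaffolds, which no comparison used. This is a signal in data outside the main measurement. The replicate 1 list had 24 such peaks and the replicate 2 list 71. None passed the IDR threshold, and the dm6 lists held none. No explanation was tested.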

How the results depend on the processing

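Alternatives with GC-matched, peaks near or far from a TSS alone, all TSSs, thinned summits, GC strata, redrawn backgrounds or random relaxed peaks were chosen after seeing the data. The promoter excess kept its direction and passed in all 10 alternatives (odds ratios 3.15 to 8.19), as did the coding exon deficit (0.0132 to 0.0629). The alternative of the strongest pooled peaks, among these 10, holds the same peaks and could not differ. Replicate overlap passed in all 6 (59.7% to 79.0%). With the 1000 strongest peaks, the promoter signal ratio (1.04) and X odds ratio (1.04) did not pass, 0 lists, 9 7-mers and 3 motifs passed, DRE at 1.21 did not pass, core promoter motif 1 was at 0.654, and the ratios of glia, EGFR and FGFR signalling and germline were 1.40, 0.578 and 0. Fewer peaks entered. Leaving out 1 replicate gave 0.826 to 1.099 for glia and 0.832 to 1.30 for germline, with the reversal without replicate 1 in each. It also gave 0.322 to 0.752 for neuroblast transcription factors, 0.311 to 0.640 for hemocyte and 0 to 0.301 for Hox. Against random positions the X odds ratio was 1.02. Lists passing numbered 2 with gene spans, 3 with all protein-coding genes and 3 without strata; glia turned to 1.03 and 1.01 under the first and second of these, and the Notch pathway to 0.952 within 500 bp. None of the reversed list values here passed. Enriched 7-mers numbered 73 within 50 bp, 753 against windows 400 bp to the side (not matched on GC) and 26 with k = 6 (fewer tested). They numbered 31 for promoter peaks and 35 for peaks farther than 1000 bp from a TSS (fewer peaks, compared with relaxed peaks of the same location). The N-box fell to 0.986 against side windows. Motifs passing were 3 among promoter peaks and 3 among peaks farther than 1000 bp from a TSS, where the E-box CAGCTG was at 0.974, DRE at 0.522 and core promoter motif 1 at 0.866; it was at 0.977 among promoter peaks. Unless given, the cause was not tested. Redrawing the background moved the number of passing motifs from 5 to 8. The depth is unknown, which limits any statement about unbound genes.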

Other observations

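The tests of highly transcribed promoters, of ACAGTGG among peaks far from a TSS, of its near-to-far ratio over that of relaxed peaks, of gene families one by one and of the strand of 7-mers were chosen after the result was seen. Gene families outside the fixed lists were compared with matched genes in the same way as the lists. Mitochondrial ribosomal protein genes had 33 of 64 members promoter-bound against 20.5 expected (ratio 1.61, permutation test, adjusted p = 0.00518). Cytochrome P450 genes had 2 of 28 against 11.3 (ratio 0.177, permutation test, adjusted p = 0.00084), cuticle protein genes 1 of 22 against 7.08 (ratio 0.141, adjusted p = 0.0101), and odorant and gustatory receptor genes 2 of 22 against 7.47 (ratio 0.268, adjusted p = 0.0273). Proteasome genes (12 of 30 against 10.9) and respiratory complex I genes (10 of 29 against 11.4) did not pass. The hypothesis that broadly expressed families in general are bound more often was tested on the mitochondrial ribosomal, proteasome and complex I genes together. The ratio was 1.29 (55 of 123 against 42.7, permutation p = 0.0224), above the 1.2 set before that test. Of the 3 families, the mitochondrial ribosomal genes passed on their own, and whether the families differ from each other was not tested. A broad excess at housekeeping promoters and one at ribosomal protein genes both stay open.

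Promoter peaks had TSSs of more than 1 gene nearby more often than relaxed ones. TSSs of more than 1 gene lay within 1000 bp of 1140 of 2345 thresholded promoter summits (48.6%), against 31.7% of 5342 relaxed promoter summits, an odds ratio of 2.04 (95% interval 1.84 to 2.25, Fisher's exact test, p = 1.56e-44). The hypothesis that promoters shared by more than 1 gene are bound more often arose from several such peaks among the strongest ones, which are part of the same data. Whether gene density or expression level accounts for it was not tested.

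For the promoter excess, a difference in GC content between thresholded and relaxed peaks would have removed it in GC-matched sets, where the odds ratio was still 3.73 (95% interval 3.41 to 4.09). Nonspecific recovery of highly transcribed promoters stays open: it predicts an excess at ribosomal protein genes, and the ratio there was 1.84, while cytochrome P450, cuticle protein and receptor genes had fewer bound promoters than matched genes. No mock precipitation was analysed here that could separate this from binding of the tagged protein, and no biological explanation was tested.

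For the cluster of summits at chn, extra copies of the locus in the transgenic line could raise the signal there. Relaxed summits in the 20 kb on each side numbered 12 on the left and 2 on the right, and neither side was tested alone. Both sides together held 14, at percentile 75.2 of comparable places, where the median was 9. The count's 95% Poisson interval of 7.65 to 23.5 reaches the percentile 95 count of 21, so the test does not decide. Inside the gene, 11 relaxed summits outside thresholded peaks lay at percentile 86.3, between the bounds set in advance. Extra copies and binding of the factor at its own gene cannot be told apart from these lists, because they hold no coverage of the control.

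For the enrichment of ACAGTGG, the promoter share of the peaks does not account for it, since among peaks farther than 1000 bp from a TSS the odds ratio was 2.84 (95% interval 2.16 to 3.74). Regional composition predicted an even spread, and copies per bp within 50 bp of the summit were 1.85 times those 150 to 250 bp away (95% interval 1.52 to 2.25), but relaxed summits gave 1.72, so this says little about the excess over them. Within 100 bp, the near-to-far ratio at thresholded summits was 1.52 times that at relaxed ones (95% interval 1.26 to 1.84), and the excess was highest 51 to 100 bp from the summit, at 3.40 (95% interval 2.94 to 3.95). It was 1.71 (1.46 to 2.01) within 50 bp and 1.59 (1.37 to 1.86) at 150 to 250 bp. ACAGTGG was picked for its excess within 100 bp over relaxed summits, so a ratio over that distance reuses the values that selected it. The counts by distance were taken over all relaxed summits outside thresholded peaks, matched neither on GC content nor on location. Whether regional composition accounts for all or part of the excess is therefore not decided. A sequence preference of the precipitated complex is a candidate explanation, and no test separated the tagged protein from a partner.

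The copies of ACAGTGG also had a direction. Of 402 copies 25 to 100 bp from a thresholded summit, 334 (83.1%, 95% Wilson interval 79.1 to 86.4) read 5' to 3' toward the summit (exact binomial test, p = 2.93e-43, adjusted over 10 7-mers 2.93e-42). The distance range was chosen from the profile around summits. The share was 87.8% in peaks farther than 1000 bp from a TSS and 78.8% in promoter peaks, 81.6% and 81.1% at the strongest summits of replicates 1 and 2, and 60.7% at relaxed summits. The 402 copies were at 402 distinct sites, and the 334 reading toward the summit had 334 distinct sequences of 61 bp around them, so they are not exact copies of a repeat. The overlapping 7-mer CACAGTG had 71.7%. The other 8 of the 10 named 7-mers lay between 47.0% and 57.9%, of which AGTGTTG, at 57.9%, passed (exact binomial test, adjusted p = 0.0225). Upstream of the copies that read toward the summit, C preceded the 7-mer in 49.7% and T in 33.2%, and G stood 2 bases before it in 62.0%. The median distance from the summit was 66 bp. No explanation of the offset or the direction was tested. The placement of summits by the peak caller bears on both, was not examined because the lists hold no coverage, and stays open.

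The share of thresholded peaks with ACAGTGG within 100 bp was 11.7%, 8.82%, 10.2%, 7.50% and 8.26% in sets of 907 or 908 peaks from the highest to the lowest signal. The Wilson interval of the first, 9.76 to 13.9, did not overlap that of the fourth, 5.96 to 9.40, and overlapped that of the last, 6.64 to 10.2. No test of a trend was made. The promoter share was 61.1% in the first set and 45.7% in the last.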
